A study of Homo sapiens with 24 samples.

How the data were processed

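RNA was measured in 24 libraries of cultured airway epithelium grown from the bronchial cells of 6 donors, 1 library for each donor, medium (PneumaCult or UNC) and exposure (filtered air or ozone). The deposited table of counts held whole numbers of reads per gene for 21028 genes with Ensembl identifiers, and every gene in it had at least 10 counts in at least 6 libraries. The submitters' processing notes name FastQC 0.12.1, cutadapt 4.1, STAR 2.7.11a, Salmon 1.10.2, R 4.3.1, DESeq2 and the genome build GRCh38.p14, without stating the role of each, the annotation release or the strand of the reads. Each deposited score of ciliated and goblet content had 1 value per donor and medium (12 distinct values), was centred and scaled to a mean of 0 and an SD of 1, and came without a statement of how the authors measured it. All columns matched the labels of 1 library. Total counts per library ran from 31093814 to 62422642. Levels are given as CPM, counts scaled to library size. Counting error weighs most on genes of low level, and the level from which it is small was not tested.

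Gene symbols came from a reference list of gene identifiers and symbols, and coordinates on GRCh38.p14 from RefSeq genes matched by symbol (17454 of the genes). GENCODE release 29 gave the chromosome and type of genes without such a match, where it held them. All 21028 identifiers had a symbol. Genes on chromosome Y, those in the regions it shares with chromosome X, XIST and TSIX (65 genes) were left out of every test and table, which left 20963. Symbols shared by more than 1 identifier occurred in 107 genes, which were kept apart by identifier.

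Replicates are donors, numbered 1 to 6. Genes were tested with the quasi-likelihood F test of edgeR 4.0.16 (glmQLFit with robust estimation, trimmed-mean scaling, the filterByExpr filter by group) in R 4.3.3, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Media were compared within donor over the 12 libraries of 1 exposure, after air and after ozone separately. Ozone was compared with air in a fit of all 24 libraries with a block for each of the 12 cultures (donor by medium) and an ozone term per medium, and the difference in response was the UNC term minus the PneumaCult term. Log2 fold changes are given with standard errors derived from the test, as the absolute log2 fold change over the square root of the F statistic. Levels in CPM are given as mean ± SD of 6 libraries, and the number of donors is that in which the pair differed in the stated direction. The comparisons, tests, gene lists and rule for named genes were fixed before the data were examined.

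Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01 and adjusted over the 24 lists of a comparison, and beside it with camera with an estimated correlation and with fry, which tests whether the genes of a list move on balance one way. The lists were NRF2 targets, heat shock response, ATF4 stress response, ER chaperones, inflammatory mediators, immediate-early genes and EGFR ligands, metallothioneins, cholesterol synthesis and uptake, AHR targets, p53 targets, interferon-stimulated, glucocorticoid-induced, retinoid-responsive and proliferation genes, ion transport genes, matrix, protease and wound genes, mitochondrially encoded genes, and markers of ciliated, basal, club and secretory, goblet, squamous, rare epithelial, and stromal, immune and endothelial cells. Over the 120 tests camera gave an adjusted p under 0.05 in 46, fry in 40 (29 of them shared) and camera with an estimated correlation in 0. Of the 24 lists, fry called 16 between media after air and 18 after ozone. For the ozone responses it called 0 in PneumaCult, 5 in UNC (4 shared with camera) and 1 for the difference.

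Named genes were, per comparison, the 10 largest positive and 10 largest negative log2 fold changes past the threshold with the same direction in all 6 donors, a mean log2 CPM of at least 1 and a protein-coding symbol. Up to 4 members of each list with the smallest adjusted p, and HMOX1, NQO1, CXCL8, IL6, FOXJ1, KRT5, SCGB1A1, MUC5AC and MUC5B, were added, and the text names a part of these; some items are not reported here. All genes past the threshold in the test of the difference are named, including those outside the rule, which were chosen after their values were seen.

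Mixed libraries were looked for after the data had been seen. Genes with at least 8-fold higher levels in 1 medium after air and at least 5 CPM were read in the libraries of the other medium, and a library was called mixed when their median level exceeded 1.5 times that of the highest air library. The share of the other medium's profile was then estimated and tested on 1220 genes not used for it. The scores were compared by an exact two-sided sign-flip test over donors, which was also added after the data had been seen.

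The tests were tried on simulated data, in which known folds were put into counts with the spread of these libraries. For 2-fold changes 77.1% were called between media after air, 85.7% for ozone in PneumaCult, 88.0% for ozone in UNC, 66.0% for the difference and 83.7% between media after ozone, with 0 in the wrong direction and 4 to 11 of the unchanged genes called in edgeR. For 1.25-fold changes the percentages were 10.0, 53.1, 53.1, 18.0 and 8.50. The pairing was checked by correlating libraries across genes after removing group means: libraries of the same donor and medium had r from 0.453 to 0.634, and those of different donors and groups from -0.265 to 0.092. Alternatives were DESeq2 1.42.0, limma-voom, RLE and upper quartile scaling, no filter and a stricter one, counts thinned to the smallest library, no block, a block by donor alone, a fit of 1 medium alone, leaving out each donor, and leaving out mixed libraries. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the tables and drew the figures.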

Results

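Gene expression was measured by RNA sequencing in primary human bronchial epithelial cells of 6 donors. Cells of each donor were grown in parallel in 2 media, PneumaCult, a commercial airway differentiation medium, and a medium labelled UNC, and were kept at the air-liquid interface for 28 to 35 days. At the air-liquid interface the apical side of the cell layer faces air, and basal cells give rise to ciliated and secretory cells. Cultures were then exposed for 2 hours to 0.5 ppm ozone, an oxidant gas, or to filtered air, and were collected 2 hours later. The data comprised 24 libraries in 4 groups of 6, paired by donor. Total counts were 34529122 to 46071235 in PneumaCult after air, 31093814 to 62422642 in PneumaCult after ozone, 31906779 to 47685087 in UNC after air and 35230091 to 56042109 in UNC after ozone.

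Over all genes medium held the largest share of the summed squares of log2 CPM, 40.8%. Donor accounted for 29.9%, the combination of donor and medium for 11.6%, ozone for 2.81% and the combination of medium and ozone for 1.70%, which left 13.2%. Over the 500 most variable genes donor came first, with 38.9% against 31.7% for medium. The first principal component held 42.0% of the variance and separated the 12 PneumaCult from the 12 UNC libraries.

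**Figure D1:**
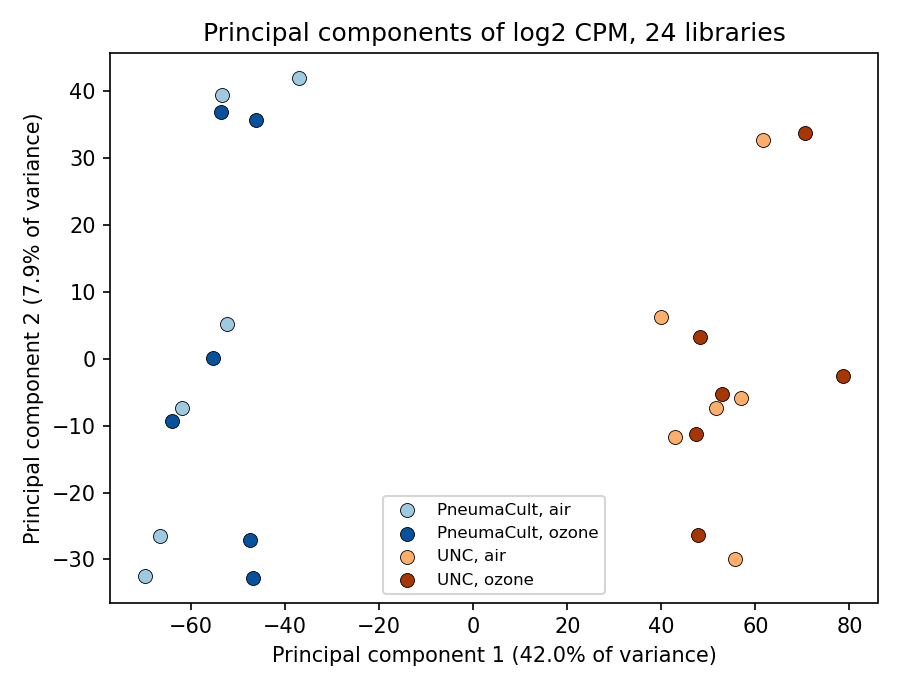
First against second principal component of log2 CPM (42.0% and 7.9% of variance), 1 point per library, 6 libraries in each of the 4 groups. The 12 PneumaCult libraries lie at negative and the 12 UNC libraries at positive values of the first component.

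The comparison of media in filtered air asked how the growth medium alone set the state of the epithelium. UNC cultures had higher levels of most NRF2 targets, basal cell markers and squamous genes. PneumaCult cultures had higher levels of cilia genes, of the gel-forming mucin MUC5AC and of most rare epithelial cell markers. The largest rise was that of SLC5A5, the sodium-iodide symporter, from 0.292 ± 0.128 CPM in PneumaCult to 129 ± 29.6 CPM in UNC (mean ± SD, n = 6), a 439-fold difference. MUC5AC was 34-fold lower in UNC, at 2.92 ± 2.22 against 88.4 ± 34.8 CPM. Of 19650 genes tested, 11158 differed between media (edgeR quasi-likelihood test, adjusted p under 0.05), 5511 higher and 5647 lower in UNC. The median fold among them was 1.49, and 2634 differed at least 2-fold, 901 higher and 1733 lower.

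SLC5A5 (ENSG00000105641.4, chromosome 19, 17871945 to 17895174, GRCh38.p14) had a log2 fold change of 8.78 ± 0.15 (SE; adjusted p = 7.44e-08), higher in UNC in 6 of 6 donors. Other genes with the largest rises in UNC, each in 6 of 6 donors, encode the salivary mineral-binding protein STATH (log2 fold change 7.87 ± 0.37), the signal transducer SMAD9 (5.01) and the metabolic coactivator PPARGC1A (4.62 ± 0.12). Others encode the proton pump ATP12A (4.51 ± 0.24), the endotoxin receptor TLR4 (4.25 ± 0.33) and the cytochrome P450 CYP2A13 (4.08 ± 0.28). CYP2A13 has a near-identical gene copy. ATP12A stood at 1405 ± 303 CPM in UNC and 68.9 ± 36.4 CPM in PneumaCult. The secreted airway proteins BPIFA1 and SCGB3A1 were higher in UNC by 4.25 ± 0.62 and 4.2 ± 0.37 log2 units. MUC5AC (ENSG00000215182.8, chromosome 11, 1157953 to 1201138) had a log2 fold change of -5.09 ± 0.35 (adjusted p = 2.68e-05), lower in 6 of 6 donors. PRRT1B (-5.15 ± 0.17), SCUBE1 (-4.81 ± 0.16), TMEM45A (-3.51 ± 0.42) and TFF3, a trefoil peptide of mucous cells (-3.41 ± 0.32), were also among the largest falls.

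Ciliated cell markers were lower in UNC as a group. Of 21 measured markers, 20 were lower and 0 higher (21 lower adjusted over the list alone; camera adjusted p = 1.62e-06, adjusted p = 0.534 with an estimated correlation). The mean log2 level of the list was lower by 0.923 ± 0.365 (SD), in 6 of 6 donors. The axonemal dynein heavy chains DNAH9 and DNAH5 and the radial spoke protein RSPH1 fell by 1.31, 1.19 and 1.17 log2 units, and DNAH9 went from 549 ± 79.9 to 225 ± 53.5 CPM. FOXJ1, the transcription factor of motile ciliogenesis, had a smaller log2 fold change of -0.47 (adjusted p = 0.0289, 5 of 6 donors). Rare epithelial cell markers were lower for 10 of 14 genes (11 adjusted over the list alone; camera adjusted p = 0.00366, adjusted p = 0.489 with an estimated correlation). Among them were FOXI1, the ionocyte transcription factor (-1.75 ± 0.12), and the chloride channel gene CFTR (-1.43 ± 0.13). Goblet cell markers went both ways, with 2 of 9 higher and 4 lower (camera adjusted p = 0.291). The mean log2 level of the list was lower by 0.95 ± 0.425 (SD) in 6 of 6 donors, and the list passed by fry with negative change (fry adjusted p = 0.00592). The mucin MUC2 was lower (-2.01 ± 0.24), while MUC5B had a log2 fold change of -0.56 ± 0.67 and was not past the threshold (adjusted p = 0.502).

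Basal cell markers were higher in UNC for 11 of 12 genes, with 0 lower (camera adjusted p = 0.00366, adjusted p = 0.636 with an estimated correlation). They included the keratin KRT15 (log2 fold change 1.56 ± 0.21), the laminin receptor subunit ITGA6 (2.38-fold, adjusted p = 0.00105) and KRT5 (0.74 ± 0.22, 5 of 6 donors). Squamous differentiation genes were higher for 12 of 19 and lower for 0 (camera adjusted p = 0.00215, adjusted p = 0.636 with an estimated correlation). S100A9 rose by 2.75 ± 0.18, S100A8 by 2.38 ± 0.26 and the crosslinking enzyme TGM1 by 1.64 ± 0.20. Of 15 club and secretory cell markers 10 were higher and 3 lower (camera adjusted p = 0.0120, adjusted p = 0.489 with an estimated correlation). The protease inhibitors SLPI and WFDC2 and the immunoglobulin transporter PIGR rose by 2.07, 1.79 and 1.01 log2 units. SCGB1A1, the classical club cell protein, had a log2 fold change of -1.22 ± 0.43 (adjusted p = 0.0405, 5 of 6 donors). Proliferation genes were higher for 9 of 15 and lower for 1 (camera adjusted p = 0.0199, adjusted p = 0.681 with an estimated correlation), with MKI67 at 1.29 ± 0.22. The proliferation list was not past the threshold by fry (fry adjusted p = 0.0546).

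NRF2 targets, the oxidant defence genes, were higher in UNC air cultures for 22 of 27 members and lower for 2 (the same counts adjusted over the list alone; camera adjusted p = 1.18e-05, adjusted p = 0.467 with an estimated correlation). The NADPH-producing enzyme ME1 rose by 1.69 log2 units, and HMOX1, heme oxygenase, by 1.60 ± 0.14, from 8.07 ± 0.98 to 24.8 ± 4.98 CPM. NQO1 was near the threshold (0.24, adjusted p = 0.0493, 5 of 6 donors). AHR targets were higher for 4 of 6 and lower for 1 (camera adjusted p = 0.0311, adjusted p = 0.467 with an estimated correlation). The cytochromes CYP1A1 and CYP1B1 rose by 8.25 ± 0.31 and 2.65 ± 0.27 log2 units, and the aldehyde dehydrogenase ALDH3A1 by 2.61 ± 0.26, from 324 ± 110 to 1930 ± 458 CPM. Metallothioneins were higher for 4 of 6 (camera adjusted p = 0.0311, adjusted p = 0.467 with an estimated correlation), including MT2A (1.11 ± 0.09) and MT1X (2.81 ± 0.10), which has near-identical relatives. Ion transport genes were higher for 9 of 16 and lower for 1 (camera adjusted p = 0.0101, adjusted p = 0.467 with an estimated correlation). The epithelial sodium channel subunit SCNN1A rose by 1.23 ± 0.08 and the carbonic anhydrase CA12 by 1.09 ± 0.08. Glucocorticoid-induced genes were higher for 5 of 12 and lower for 1 (camera adjusted p = 0.154, fry adjusted p = 3.55e-04), with the transcription factor KLF9 at 3.06 ± 0.14 and the kinase SGK1 at 1.43 ± 0.10. Interferon-stimulated genes were higher for 3 of 17 and lower for 7 (camera adjusted p = 0.121, fry adjusted p = 0.0145), and IFI27 fell by 1.93 log2 units. Inflammatory mediators were higher for 4 of 21 and lower for 2 (3 and 1 adjusted over the list alone; camera adjusted p = 0.463), and the neutrophil chemokine CXCL8 was not past the threshold (0.39 ± 0.25, adjusted p = 0.212).

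The deposited scores of ciliated and goblet content, scaled to a mean of 0 and an SD of 1 over the cultures, were also compared within donor. The ciliated score was 0.703 ± 0.562 in PneumaCult and -0.703 ± 0.894 in UNC, a difference of -1.41 ± 1.07 that was negative in 6 of 6 donors (exact two-sided sign-flip p = 0.0312, the smallest that 64 sign flips allow; adjusted p = 0.0624 over the 2 scores). The goblet score was 0.673 ± 0.945 in PneumaCult and -0.673 ± 0.565 in UNC, lower in UNC in 5 of 6 donors (exact two-sided sign-flip p = 0.0625, adjusted p = 0.0625). Among the genes named, 4 lost the threshold when single donors were left out: FOXJ1 and KRT5 without replicates 1, 2, 4 or 5 (adjusted p from 0.0531 to 0.0903), NQO1 without replicates 1, 2, 3, 5 or 6 (0.0542 to 0.138), and SCGB1A1 without the same replicates (0.0639 to 0.102).

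**Figure D2:**
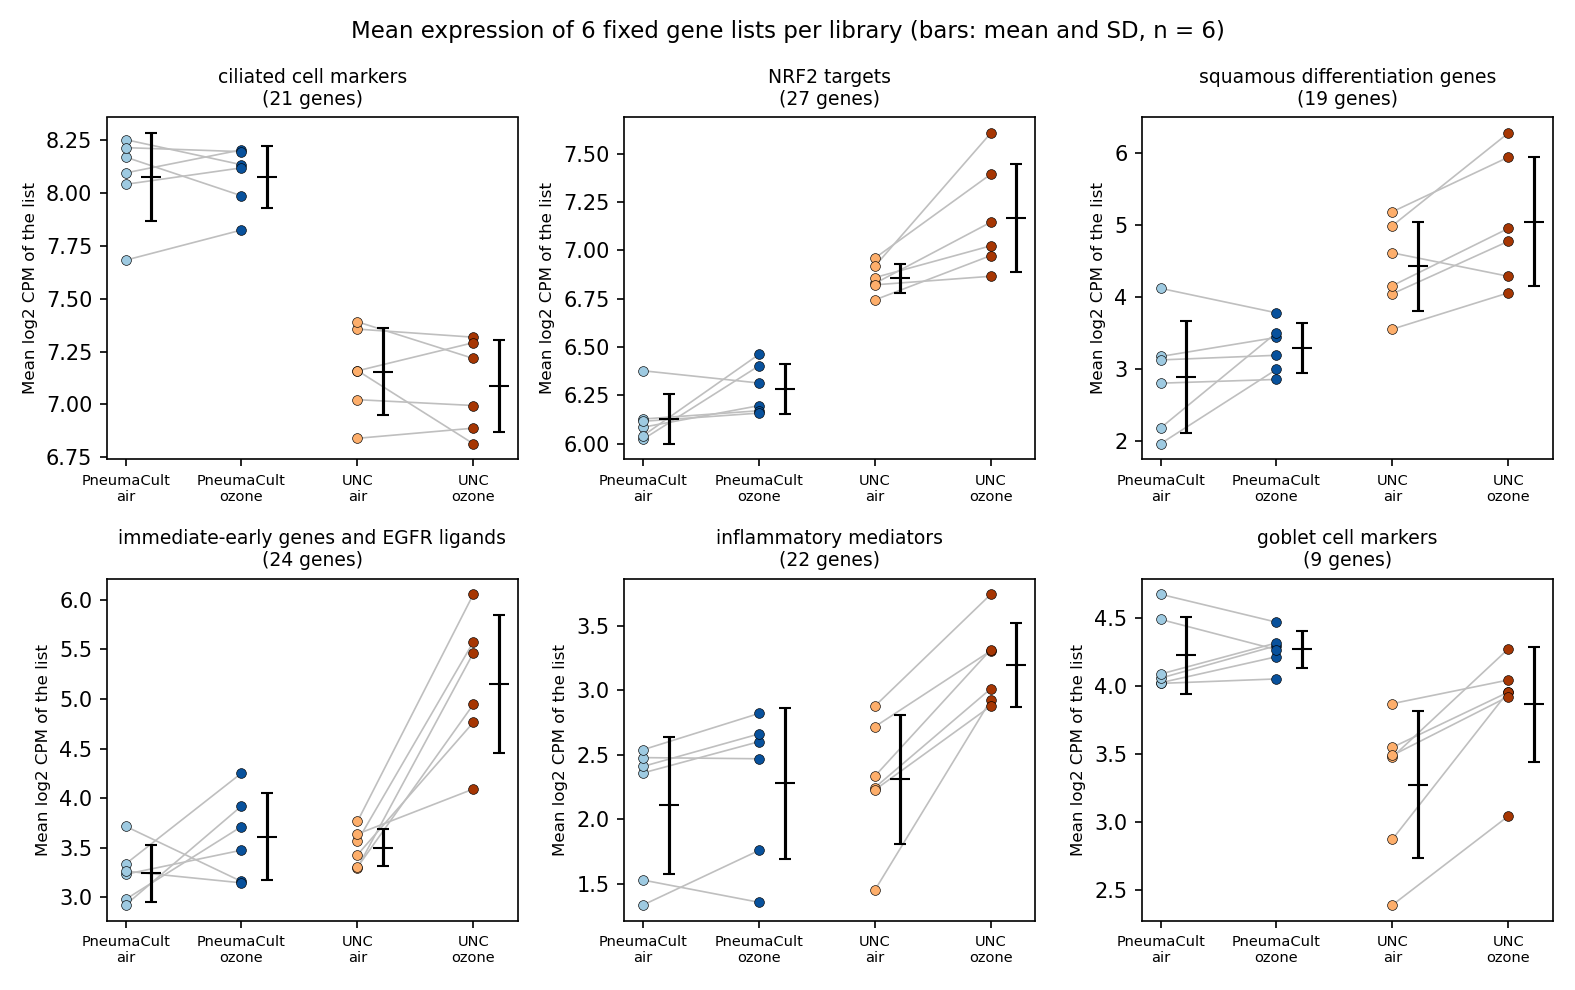
Mean log2 CPM of 6 gene lists per library in the 4 groups; grey lines join libraries of one donor, and bars give the mean ± SD of 6 libraries. Ciliated markers were lower and NRF2 targets and squamous genes higher in UNC, and immediate-early genes and inflammatory mediators stood highest in UNC after ozone.

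Genes that mark one medium appeared at raised levels in 3 ozone libraries of the other medium. A set of 38 genes with at least 8-fold higher levels in UNC than in PneumaCult after air stood at 5.63 to 6.22% of their UNC level in the 6 PneumaCult air libraries and at 5.62 to 6.41% in 4 PneumaCult ozone libraries, and at 18.3 and 26.3% in the other 2. A set of 25 genes high in PneumaCult stood at 4.91 to 10.3% of their PneumaCult level in the UNC air libraries and at 4.3 to 9.92% in 5 UNC ozone libraries, but at 23.0% in the remaining one. These 3 libraries came from 2 donors and are called mixed libraries here. Gene counts without them are given for each comparison they enter, and list counts for a part of the lists.

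**Figure D3:**
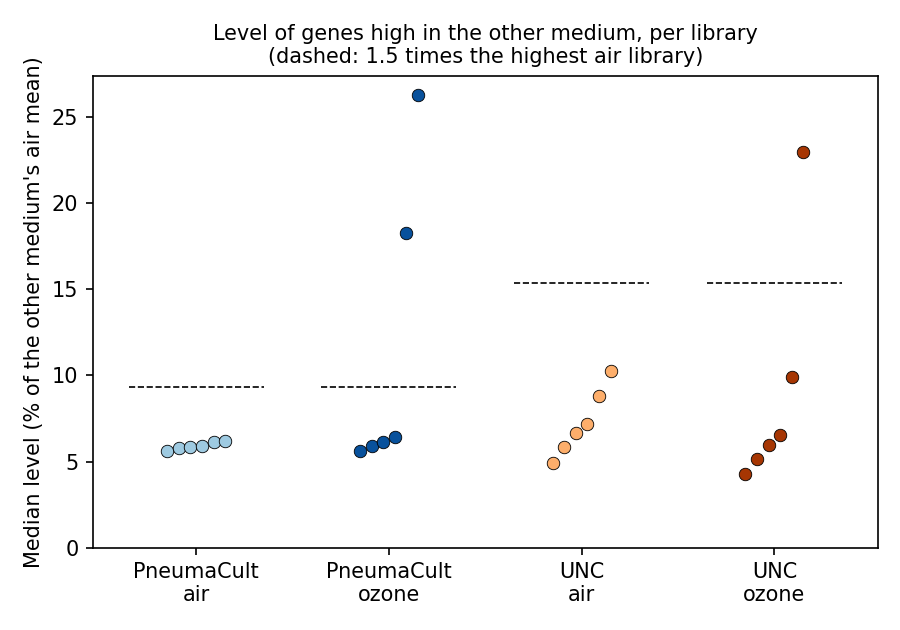
Median level of the genes that mark the other medium, in percent of their level in that medium after air, 1 point per library in the 4 groups. Dashed lines lie at 1.5 times the highest air library (9.32 and 15.39%), and 2 PneumaCult ozone libraries and 1 UNC ozone library lie above them.

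The comparison of ozone with air within UNC cultures asked what ozone changed within hours in that medium. Of the immediate-early genes 23 of 24 rose, of the inflammatory mediators 10 of 22, of the NRF2 targets 9 of 27 and of the heat shock genes 8 of 17. Without the mixed pairs these counts were 22, 13, 9 and 4. The gel-forming mucins MUC5AC and MUC2 rose as well. FOSB, a component of the AP-1 transcription factor, went from 1.35 ± 0.46 CPM after air to 23.5 ± 16.3 CPM after ozone (n = 6). HMOX1 went from 24.8 ± 4.98 to 114 ± 67.5 CPM and CXCL8 from 30.4 ± 10.7 to 113 ± 40.2 CPM. Of 20740 genes tested, 1958 changed (edgeR, adjusted p under 0.05), 1241 up and 717 down, with a median fold of 1.2. At least 2-fold changes numbered 117, of which 103 were rises. The share of rises was 63.4% with trimmed-mean scaling and 50.1% with upper quartile scaling (1110 up, 1105 down).

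Immediate-early genes and EGFR ligands rose nearly as a whole, 23 of 24 over all genes tested and 24 of 24 adjusted over the list alone (camera adjusted p = 3.87e-23, adjusted p = 0.264 with an estimated correlation). The list's mean log2 level rose by 1.65 ± 0.684 (SD) in 6 of 6 donors. FOSB (ENSG00000125740.15, chromosome 19, 45467996 to 45475179) had a log2 fold change of 3.87 ± 0.57 (adjusted p = 0.00376) and FOS of 3.17 ± 0.54, each in 6 of 6 donors. The nuclear receptor NR4A1 (2.77 ± 0.47), the AP-1 component FOSL1 (2.49 ± 0.48), the phosphatases DUSP5 (2.46 ± 0.45) and DUSP6 (2.05 ± 0.36) and the EGFR ligand AREG (2.14 ± 0.35) followed. The transcription factor KLF2, outside the list, rose by 1.96 ± 0.28 log2 units. Without the mixed pairs of both media, 22 of the 24 members rose (camera adjusted p = 2.91e-22, adjusted p = 0.288 with an estimated correlation).

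Inflammatory mediators rose for 10 of 22 members (16 adjusted over the list alone) and fell for 0 (camera adjusted p = 5.74e-12, adjusted p = 0.0699 with an estimated correlation; list mean up by 0.887 ± 0.320 in 6 of 6 donors). CXCL8 (ENSG00000169429.12, chromosome 4, 73740569 to 73743716) rose by 1.93 ± 0.27 (adjusted p = 0.00343), the epidermal interleukin IL36G by 2.34 ± 0.33, the cytokine LIF by 1.95 ± 0.24, the prostaglandin synthase PTGS2 by 1.09 ± 0.12 and the adhesion molecule ICAM1 by 0.56 ± 0.09. IL6 had a log2 fold change of 0.99 ± 0.40 in 5 of 6 donors and was not past the threshold (adjusted p = 0.135).

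NRF2 targets rose for 9 of 27 (11 adjusted over the list alone; camera adjusted p = 3.39e-05, adjusted p = 0.511 with an estimated correlation). HMOX1 (ENSG00000100292.18, chromosome 22, 35381096 to 35394207) led with 2.04 ± 0.31 (adjusted p = 0.00418, 6 of 6 donors), followed by OSGIN1 (1.41 ± 0.25), the transcription factor MAFG (0.56 ± 0.08) and thioredoxin reductase TXNRD1 (0.48 ± 0.08). Heat shock genes rose for 8 of 17 (10 adjusted over the list alone; camera adjusted p = 3.39e-05, adjusted p = 0.511 with an estimated correlation). They included the chaperones HSPA1B (1.33 ± 0.27), whose near-identical copy is HSPA1A, and DNAJA1 (0.30 ± 0.07). Without the mixed pairs 4 of the 17 heat shock genes rose (camera adjusted p = 3.78e-06, adjusted p = 0.373 with an estimated correlation). The ATF4 stress response rose for 7 of 16 (8 up and 1 down adjusted over the list alone; camera adjusted p = 2.53e-05, adjusted p = 0.490 with an estimated correlation). Without the mixed pairs 5 of its genes rose and 1 fell (camera adjusted p = 3.09e-05, adjusted p = 0.373 with an estimated correlation, fry adjusted p = 0.0741). ATF3 rose by 1.64 ± 0.26, the phosphatase regulator PPP1R15A by 0.81 ± 0.13 and CEBPB by 0.54 ± 0.07.

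Among goblet cell markers, 3 of 9 rose after ozone (5 adjusted over the list alone; camera adjusted p = 2.93e-04, adjusted p = 0.287 with an estimated correlation). These were MUC5AC, which rose by 2.45 ± 0.38, from 2.92 ± 2.22 to 16.6 ± 14 CPM, MUC2 by 1.17 ± 0.21, and SPDEF, a transcription factor of goblet cells, by 0.67 ± 0.11. The mixed UNC library held 40.6 CPM of MUC5AC, a gene of high level in PneumaCult, against 3.99 to 24.9 CPM in the other 5. In the fit without the mixed pairs of both media the rise was 2.18 (edgeR adjusted p = 0.0361). For MUC2 (ENSG00000198788.9, chromosome 11, 1074874 to 1110508) the rise without those pairs was 1.04 (adjusted p = 0.0194). Squamous genes rose for 4 of 19 (9 adjusted over the list alone; camera adjusted p = 1.94e-05, adjusted p = 0.511 with an estimated correlation). They included KRT6B (1.13 ± 0.20) and SPRR2A (1.51 ± 0.29, 5 of 6 donors), which both have near-identical relatives. Without the mixed pairs 3 of the 19 squamous genes rose (camera adjusted p = 2.31e-06, adjusted p = 0.373 with an estimated correlation). The protease PLAU and its receptor PLAUR, of the matrix and wound list, rose by 1.14 and 1.56 log2 units. The stress kinase PLK3 of the p53 list rose by 1.07 and the amino acid transporter SLC6A14 of the ion transport list by 0.61.

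Falls were smaller. RBBP8NL (-0.78 ± 0.07, adjusted p = 3.51e-05), the prostaglandin receptor PTGFR (-0.83 ± 0.16), the splicing factor RBM20 (-0.81 ± 0.16), the sodium channel subunit SCNN1G (-0.71 ± 0.09) and the monooxygenase FMO2 (-0.56 ± 0.14) fell, each in 6 of 6 donors. Proliferation genes fell for 2 of 15 (3 adjusted over the list alone; camera adjusted p = 0.0141, adjusted p = 0.655 with an estimated correlation), with TOP2A at -0.34 ± 0.07. Without the mixed pairs 4 of 15 fell (camera adjusted p = 2.21e-06, adjusted p = 0.295 with an estimated correlation). The retinoic acid receptor RARB (-0.28), the retinal reductase DHRS3 (-0.31) and the p53 target SESN1 (-0.34 ± 0.06) also fell. Ciliated, club, rare cell, interferon, metallothionein and mitochondrially encoded lists had 0 members past the threshold in edgeR (camera adjusted p from 0.0666 to 0.741). With all libraries fry called 5 lists, 4 of them among the 9 that camera called. NRF2 targets and heat shock genes had a fry adjusted p of 0.0647 each. Without the mixed pairs 13 rather than 9 lists were past the threshold by camera. Newly past were ciliated markers with negative change (0.00802) and club markers (0.00802), glucocorticoid-induced genes (0.00875) and AHR targets (0.0206) with positive change. With an estimated correlation those adjusted p were 0.682, 0.373, 0.373 and 0.288.

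Without the mixed pairs of both media, 1369 genes changed in UNC (899 up, 470 down), of which 1161 were among the 1958. Without both donors with a mixed library 258 changed, 233 of them shared. In the smaller set of donors 20 of the 47 genes named as changed in UNC, here or in the closing section, stayed past the threshold, such as HMOX1 (1.83, adjusted p = 0.0257), and 27 did not. FOSB (3.6, adjusted p = 0.104), CXCL8 (1.92, adjusted p = 0.0911), MUC5AC (1.63, adjusted p = 0.0911) and MUC2 (0.77, adjusted p = 0.0819) were among the 27, as were FOS (3.06), NR4A1 (2.64), DUSP5 (2.24), AREG (1.86), KLF2 (1.88) and ATF3 (1.61), with adjusted p from 0.0575 to 0.141 and fewer donors in the fit. PTGFR (-0.77, adjusted p = 0.0697) and FMO2 (-0.63, adjusted p = 0.0731) were no longer past the threshold without the mixed pairs. The count fell to 818, 650 and 668 genes without replicates 1, 2 and 3. Leaving out 1 donor ended the call of 10 of the genes named here: FMO2 (any replicate but 5, adjusted p up to 0.104), FOSL1 (1 or 2; up to 0.0720), DUSP6 (2; 0.0521), PTGFR (3; 0.0502) and RBM20 (1 or 3; up to 0.0558). The others were HSPA1B and DNAJA1 (1, 2 or 3; up to 0.0777), SPRR2A (2 or 3; up to 0.0577), DHRS3 (2; 0.0812) and TOP2A (1 or 3; up to 0.0520).

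The same exposure of PneumaCult cultures asked whether ozone acted alike in that medium. Few genes passed the threshold, and changes were small. RSRP1 fell from 88.1 ± 13.4 to 63.5 ± 12.5 CPM (n = 6), and the only rise was that of LANCL2, from 29.6 ± 1.19 to 34.0 ± 0.58 CPM. Of 20740 genes tested, 35 changed (edgeR, adjusted p under 0.05), 1 up and 34 down, with a median fold of 1.26, and 2717 had an unadjusted p under 0.05 where chance gives about 1037. With DESeq2 262 genes changed, of which 17.9% were rises, against 2.9% with edgeR. RLE scaling gave 3 genes, upper quartile scaling 1, no filter 2 and thinned counts 1, each with at most 1 of the 9 genes named here as changed, and a fit without the culture block gave 3 rises and 0 of the 9.

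The 2 falls of at least 2-fold were those of SLX1A-SULT1A3 (log2 fold change -1.13, adjusted p = 0.0463), a read-through gene with near-identical copies, and PPFIA4 (-1.08, adjusted p = 0.0446), both outside the rule for named genes and chosen after their values were seen. Without the mixed pairs these were -1.28 and -0.88 (adjusted p = 0.124 and 0.148). Among protein-coding genes of sufficient level with the same direction in all donors, the largest falls included the collagen gene COL27A1 (log2 fold change -0.48 ± 0.08, adjusted p = 0.0427), RSRP1 (-0.48 ± 0.09), LMNTD2 (-0.45 ± 0.08), SH3D21 (-0.39 ± 0.06), the cytokine IL16 (-0.36 ± 0.06) and TBCK (-0.33 ± 0.06), and LANCL2 rose by 0.20 ± 0.04, each in 6 of 6 donors. HMOX1 stood at 8.07 ± 0.98 CPM after air and 15.6 ± 7.45 CPM after ozone, a log2 fold change of 0.84 ± 0.34 that was positive in 6 of 6 donors and not past the threshold (adjusted p = 0.325). FOSB (1.32 ± 0.59, adjusted p = 0.382, 5 of 6 donors) and CXCL8 (0.44 ± 0.28, adjusted p = 0.537) were not past it either.

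In PneumaCult no list had a member past the threshold over all genes, but 5 lists were past it as groups, with positive change. These were NRF2 targets (camera adjusted p = 1.06e-04), immediate-early genes (5.08e-04), club and secretory cell markers (5.02e-04), squamous genes (1.24e-04) and AHR targets (0.0270). In edgeR adjusted over the list alone, 1 NRF2 target, 3 club markers and 2 AHR targets passed, and 0 genes of the other 2 lists. With an estimated correlation the adjusted p was 0.873, 0.873, 0.764, 0.873 and 0.764. With fry it was 0.641, 0.744, 0.251, 0.641 and 0.232, so that none of the 5 lists passed. Several of their genes are high in UNC, and 2 of the 6 PneumaCult ozone libraries were mixed. CYP1A1 (ENSG00000140465.15, chromosome 15, 74719542 to 74725528) stood at 2.68 and 3.22 CPM in these 2 and at 0 to 0.0922 CPM in the other 4. Its log2 fold change was 4.68 ± 0.92 (adjusted p = 0.0711) over all 6 pairs and -0.02 (adjusted p = 0.999) without the mixed pairs. For ALDH3A1 the values were 0.44 and 0.10, for BPIFA2, a secreted protein of the club list, 1.02 and 0.41, and for HMOX1 0.84 and 0.40, none past the threshold. Without the mixed pairs of both media the 5 lists had camera adjusted p of 0.412, 0.771, 0.172, 0.961 and 0.417 in the same order. Instead ciliated markers were past it with positive change (camera adjusted p = 0.0106), and proliferation (0.0172) and basal genes (0.0191) with negative change, all with an adjusted p = 0.989 with an estimated correlation.

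Without the mixed pairs 0 genes changed in PneumaCult (edgeR; 2677 at an unadjusted p under 0.05). The same was true without replicates 1, 2, 4 or 6 (0 genes each in edgeR, with 1782 to 2981 at an unadjusted p under 0.05), and 22 and 6 genes changed without replicates 3 and 5. All 35 genes kept their direction in each of these. This was nearly fixed in advance, since 33 of them changed the same way in all 6 pairs. Without the mixed pairs COL27A1, LMNTD2, SH3D21 and IL16 had log2 fold changes of -0.5, -0.38, -0.35 and -0.3 (edgeR adjusted p from 0.124 to 0.196).

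The test of the difference asked which genes responded to ozone unlike between the media. The mucin MUC2 and the kinases PLK3 and IRAK2 were among the few genes past the threshold, with a more positive response in UNC. MUC2 rose by 1.17 log2 units in UNC and had a change of -0.37 in PneumaCult, a difference of 1.54 ± 0.28 (adjusted p = 0.0455). For PLK3 the values were 1.07 and -0.27, a difference of 1.35 ± 0.21 (adjusted p = 0.0446), and for IRAK2, a kinase of interleukin-1 and Toll-like receptor signalling, 0.98 and 0.09, a difference of 0.89 ± 0.12 (adjusted p = 0.0117). Of 20740 genes 18 passed the threshold (edgeR; 2341 at an unadjusted p under 0.05), 16 with a more positive and 2 with a more negative response in UNC, all in the same direction in 6 of 6 donors.

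The other genes with a more positive response in UNC included the antisense RNA IER3-AS1 (1.53 ± 0.20; the strand of the reads was not stated) and the endocytic adaptor DAB2 (0.92 ± 0.16). Further ones were the metalloprotease ADAM8 (0.83 ± 0.13), the snoRNA host genes SNHG15 (0.68 ± 0.12) and SNHG1 (0.45 ± 0.08), and CMYA5 (0.60 ± 0.09). ANKRD36B (0.53 ± 0.09) has near-identical copies, and its response was -0.36 in PneumaCult and 0.17 in UNC. Smaller differences were those of KSR1 and INF2 (0.44 each), TRIB2 (0.40), ZNF121 (0.39), the transcription factor CEBPD (0.36) and ANKLE2 (0.32). PXMP4, a peroxisomal membrane protein (-0.39 ± 0.06), and TMEM37 (-0.68 ± 0.10) had a more negative response in UNC. MUC5AC, LIF, PTGS2, IER3, DUSP6 and CXCL8 had differences of 2.78, 1.73, 0.90, 1.23, 2.15 and 1.48 log2 units, positive in 6 of 6 donors, with adjusted p from 0.0750 to 0.209.

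As groups, immediate-early genes had a more positive response in UNC, with 0 of 24 members past the threshold over all genes and 19 adjusted over the list alone (camera adjusted p = 1.88e-18, adjusted p = 0.436 with an estimated correlation; mean difference 1.28 ± 0.945 SD, 6 of 6 donors). Inflammatory mediators had 0 members past it and 6 adjusted over the list alone (camera adjusted p = 7.90e-10, adjusted p = 0.131 with an estimated correlation; 0.717 ± 0.344, 6 of 6 donors). ATF4 (4 members adjusted over the list alone), heat shock (1 member) and goblet genes (2 members) had camera adjusted p of 1.11e-04, 1.36e-04 and 0.0107 with a more positive response, and ciliated markers 0.0464 with a more negative one. With an estimated correlation those adjusted p were 0.618, 0.817, 0.597 and 0.961. By fry 1 of the 24 lists passed, inflammatory mediators (adjusted p = 0.0140), and immediate-early genes did not (fry adjusted p = 0.0770). Without the mixed libraries and their air partners 12 rather than 6 lists were past the threshold by camera, and ciliated markers had an adjusted p of 7.82e-06. Newly past were NRF2 targets (3.35e-04), squamous (3.36e-05), interferon-stimulated (0.00351), glucocorticoid-induced (0.0264) and p53 genes (0.0435) with a more positive and proliferation genes (0.0177) with a more negative response in UNC. With an estimated correlation none of the 12 had an adjusted p under 0.298.

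Without the 3 mixed libraries and their air partners 3 genes passed the threshold (2690 at an unadjusted p under 0.05): IRAK2 (0.98, adjusted p = 0.0422), IER3-AS1 (1.65, adjusted p = 0.0422) and CCNL1, which was named after its values were seen. MUC2 (1.33, adjusted p = 0.185) and PLK3 (1.30, adjusted p = 0.180) did not. Leaving out each donor gave 0, 4, 1, 2, 75 and 21 genes without replicates 1 to 6, and the call was lost without replicates 1, 3 or 4 for IRAK2 (adjusted p from 0.0532 to 0.129), 1 to 4 for MUC2 (0.142 to 0.267) and any but 5 for PLK3 (0.0680 to 0.243).

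Across genes, which are not independent replicates, the ozone responses of the media had a Pearson r of 0.230 and a Spearman rho of 0.328 over all 20740 genes tested, with 64.8% of genes changing in the same direction. Over the 1984 genes past the threshold in either medium r was 0.603 and rho 0.621, with 82.8% in the same direction and a slope of PneumaCult on UNC of 0.223. Without the mixed pairs r was 0.164 over all genes, and over the 1369 genes then past the threshold in UNC it was 0.465, with 74.4% in the same direction and a slope of 0.15. Both gene sets were chosen almost wholly by their change in UNC, which favours larger changes there and a low slope. Over all genes tested the slope was 0.2, with median absolute log2 fold changes of 0.078 in PneumaCult and 0.113 in UNC. Over the 35 genes past the threshold in PneumaCult, a choice that favours that medium, the medians were 0.331 and 0.128. Of the 34 genes that fell in PneumaCult, 9 also fell in UNC, where 1.18 would be expected if the calls were independent. They are not, since both sets come from 1 fit with the same donors and estimate of spread.

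**Figure D4:**
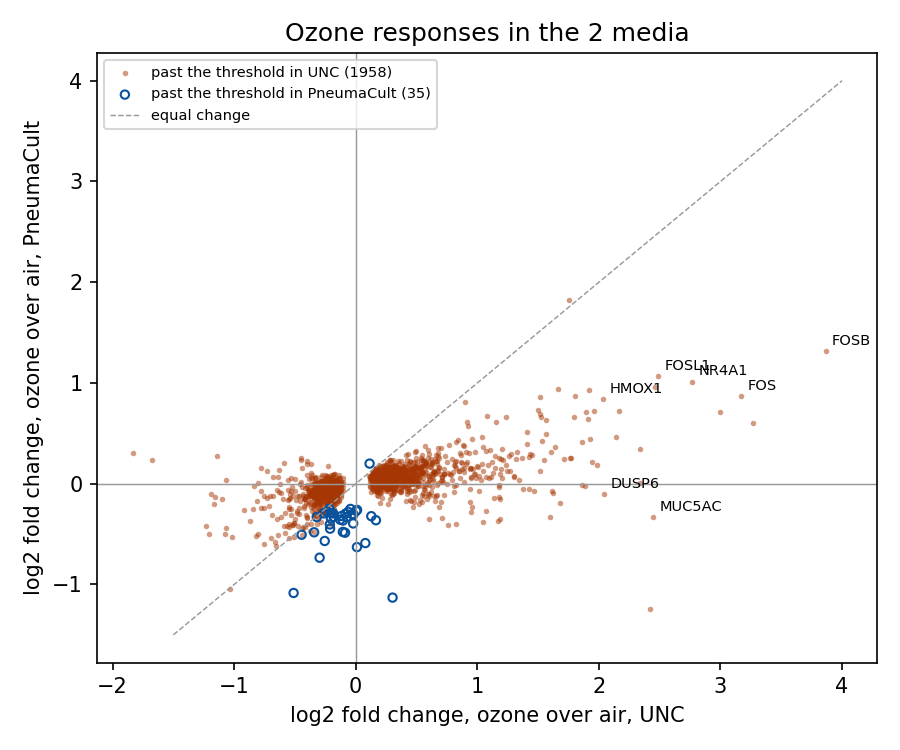
Log2 fold change of ozone over air in UNC (x axis) against PneumaCult (y axis), with 1 point per gene for the 1958 genes past the threshold in UNC and open circles for the 35 in PneumaCult. Most labelled genes lie right of the dashed line of equal change, with a larger change in UNC.

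The comparison of media after ozone asked how the cultures differed once exposed. In UNC cultures 20 of 24 immediate-early genes, 21 of 27 NRF2 targets and 12 of 22 inflammatory mediators were higher, and in PneumaCult cultures all 21 ciliated markers were. HMOX1 stood at 114 ± 67.5 CPM in UNC and 15.6 ± 7.45 CPM in PneumaCult (n = 6), and CXCL8 at 113 ± 40.2 and 31.7 CPM. Of 19443 genes tested, 11030 differed (edgeR), 5304 higher and 5726 lower in UNC, with 2886 at least 2-fold. Without the donors with a mixed library 8744 differed, 8391 of them shared. In that smaller set of donors 18 of 24 immediate-early genes, 17 of 27 NRF2 targets and 11 of 22 inflammatory mediators were higher in UNC, and 20 of 21 ciliated markers were lower.

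Immediate-early genes were higher in UNC for 20 of 24 and lower for 0 (22 higher adjusted over the list alone; camera adjusted p = 2.11e-06, adjusted p = 0.542 with an estimated correlation). After air 11 were higher and 4 lower (camera adjusted p = 0.22). DUSP4 was higher by 1.96 ± 0.27 log2 units, and the stress gene IER3 by 1.87 ± 0.18. Inflammatory mediators were higher for 12 of 22 and lower for 1 (camera adjusted p = 0.00609, adjusted p = 0.622 with an estimated correlation). The list's fry adjusted p was 0.0365 with all donors and 0.143 without the donors with a mixed library. IL1B was higher by 2.49 ± 0.22, IL36G by 2.59 ± 0.40, CXCL8 by 1.84 ± 0.42 and IL6 by 2.68 ± 0.80 (adjusted p = 0.0209, 5 of 6 donors). IL6 lost the threshold without replicate 5 (2.54, adjusted p = 0.0627). HMOX1 was higher by 2.79 ± 0.30 (adjusted p = 1.71e-04), with 21 of 27 NRF2 targets higher and 2 lower (camera adjusted p = 2.16e-05, adjusted p = 0.542 with an estimated correlation), and PLAUR by 2.06 ± 0.17.

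All 21 ciliated markers were lower in UNC after ozone (camera adjusted p = 8.92e-08, adjusted p = 0.542 with an estimated correlation). Squamous and basal genes were higher for 14 of 19 and 11 of 12 (camera adjusted p = 1.59e-04 and 8.75e-04, each with an adjusted p = 0.542 with an estimated correlation). Without the donors with a mixed library these were 11 of 19 and 8 of 12 (camera adjusted p = 3.55e-04 and 0.00594, each with an adjusted p = 0.639 with an estimated correlation). MUC5AC was lower by 2.44 log2 units, at 16.6 ± 14 against 68.6 ± 24 CPM. SLC5A5 and STATH were higher by 5.77 ± 1.17 and 5.79 ± 1.03 with all donors and by 8.57 and 8.47 without the donors with a mixed library. PRRT1B and SCUBE1 were lower by 4.88 and 4.05 with all donors and by 5.34 and 4.39 without. SLC5A5 stood at 16.2 and 28.3 CPM in the 2 mixed PneumaCult libraries and at 0.122 to 0.674 CPM in the other 4.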

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

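The tests of an ozone effect shared by donors, of mixed libraries and of a smaller response as sources of the low count in PneumaCult, and of a mixed UNC library as the source of the mucin rise were chosen after the result was seen.

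The first pattern weighed is the raised level of the other medium's genes in 2 PneumaCult and 1 UNC ozone libraries. An ozone effect shared by the donors would need all 6 ozone libraries of a medium, and 4 of 6 in PneumaCult and 5 of 6 in UNC stayed within the limit set by air, which argues against an effect in all donors but not against one in single donors. For mixed libraries, the changes of 1220 genes not used to estimate the shares (13.8, 17.0 and 8%) had slopes of 0.98, 1.08 and 0.83 on the changes expected from them. Pearson r was 0.8, 0.84 and 0.41, so that the UNC library followed the expected changes least closely. The other 9 ozone libraries had slopes from -0.85 to 0.29, slightly over the 0.25 foreseen for them, and r from -0.43 to 0.25. RNA or cells of the other medium in these libraries is thus a candidate source, while whether it entered in culture, at lysis or at library preparation was not tested.

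The second pattern is the lower number of genes changed by ozone in PneumaCult (35) than in UNC (1958). A wider spread between PneumaCult pairs is argued against by the ratio of median SDs of the pair changes, 0.75 without mixed libraries (0.107 against 0.143). Whether mixed libraries are its cause cannot be told apart with the few donors left: without both donors the counts were 0 in PneumaCult and 258 in UNC (edgeR), but 3088 and 3265 genes had an unadjusted p under 0.05, while without the mixed pairs alone, which leaves 4 pairs in PneumaCult and 5 in UNC, the counts were 0 and 1369 (2677 and 4873 at an unadjusted p under 0.05). A smaller response in PneumaCult stays open as well: the change of the immediate-early list in the 4 donors with both pairs unmixed was larger in UNC by 1.45 ± 1.06 (SD), which only restates a difference that all 6 donors showed.

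The third pattern is the rise of MUC5AC and MUC2 after ozone in UNC, since both genes are high in PneumaCult. In the fit without the mixed pairs at least 89% of the log2 size of the rise was kept for both genes. Since 1 of 6 UNC pairs was left out for this, most of the rise was nearly bound to stay. The rise was present in the UNC pairs without a mixed library, which argues against that library as its only source. Without both donors with a mixed library neither gene was past the threshold, with fewer donors in the fit. MUC2 stood at 1.65 CPM in the mixed library and at 0.751 to 3.96 CPM in the other 5, so that it was not the highest. An ozone response of these mucins in UNC stays open as a hypothesis, and the difference from PneumaCult for MUC2 was 1.54 with all libraries (adjusted p = 0.0455) and 1.33 without the mixed ones (adjusted p = 0.185), a call that was also lost without replicates 1, 2, 3 or 4.

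The difference in ozone response between media passed the test for 18 genes, in log2 units of UNC minus PneumaCult: MUC2 1.54, IER3-AS1 1.53, PLK3 1.35, DAB2 0.92, IRAK2 0.89, ADAM8 0.83, SNHG15 0.68, CMYA5 0.60, ANKRD36B 0.53, SNHG1 0.45, KSR1 0.44, INF2 0.44, TRIB2 0.40, ZNF121 0.39, CEBPD 0.36, ANKLE2 0.32, PXMP4 -0.39 and TMEM37 -0.68.

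In 11 of 116 groups of 6 libraries 1 library stood far from the others, where chance gives about 1 in 20 (5.8), judged by its gap to the nearest library as a share of the group's range against the 95% limit of Dixon's test. The number of genes detected in PneumaCult after air had a share of 0.69, with 1 library at 20870 and the others at about 20810 to 20830. The percentage of mitochondrial counts in UNC had 1 library at 14.73% after air (0.639; others 10.08 to 11.76%) and 1 at 9.317% after ozone (0.632; others 11.53 to 12.82%). The mitochondrially encoded list after air in UNC stood at 12.88 log2 CPM in 1 library (0.626; others 12.31 to 12.52). The percentage of counts in the top 20 genes in UNC after ozone was 11.95% in 1 library (0.752; others 14.38 to 15.18%). Mean log2 CPM of NRF2 targets in PneumaCult after air was 6.377 in 1 library (0.704; others 6.023 to 6.128), and that of ciliated cell markers 7.683 (0.629; others 8.042 to 8.254). In UNC after ozone retinoid-responsive genes stood at 5.482 in 1 library (0.772; others 4.882 to 5.019) and goblet cell markers at 3.042 (0.715; others 3.919 to 4.27). Rare epithelial cell markers in UNC had 1 library at 0.4497 after air (0.669; others -0.5466 to -0.2164) and 1 at 0.7132 after ozone (0.69; others -0.5493 to -0.1576).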

How the results depend on the processing

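The alternatives that leave out mixed libraries were chosen after seeing the data; the others were set before. The counts between media kept within 1.5 times the reported count under every alternative run, 9680 to 11603 after air and 9366 to 11371 after ozone when each donor was left out. The count in PneumaCult (35) was the least stable: 262 with DESeq2, 55 with limma-voom, 3 with RLE and 1 with upper quartile scaling, 2 without a filter, 1 with thinned counts, 0 to 22 without single donors, and 0 without the mixed pairs or without their donors. From the PneumaCult libraries alone it was 26. The count in UNC (1958) was 650 to 2565 without single donors, 258 without the donors with a mixed library and 856 from the UNC libraries alone. The difference (18) was 165 with DESeq2, 7 with RLE scaling, 6 without a filter, 28 with the stricter filter, 0 to 75 without single donors, 3 without the mixed pairs and 1 without their donors. Fewer libraries entered where donors or pairs were left out; for the others the cause was not tested.

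Without a replicate block for the culture, the counts were 374 in UNC, 3 in PneumaCult and 0 for the difference (edgeR; 804 at an unadjusted p under 0.05), and with a block by donor alone 854, 0 (1537) and 0 (1320). The number of list calls by camera fell from 46 to 0 of 120 with an estimated correlation. The correlation of the responses was 0.457 over genes with a mean log2 CPM of at least 3, 0.164 without the mixed pairs and 0.167 to 0.25 without single donors. The percentage of squares by medium was 35.87 with a prior count of 0.5, 31.67 over the 500 most variable genes (where donor, at 38.87, exceeded it) and 42.48 without the donors with a mixed library. The change of CYP1A1 in PneumaCult turned from 4.68 to -0.02 without the mixed pairs and to -0.02 without their donors.

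For the 154 named results by gene, 2176 of 2542 alternatives kept direction and side of the threshold, 351 kept direction but were no longer past it, 13 were newly past it and 2 turned. Between media these were 876 of 900 after air and 205 of 206 after ozone, for ozone 767 of 861 in UNC and 144 of 269 in PneumaCult, and for the difference 184 of 306. Thinning to the smallest library (31093814 counts) left 1823 genes changed in UNC but 1 in PneumaCult, where 8 of 9 named genes were no longer past the threshold and 2819 genes, against 2717, had an unadjusted p under 0.05. Up to what level depth limits a gene was not tested.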

Other observations

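All tests in this part were set before the result was seen, except those without mixed libraries.

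Beyond the groups in the report, ER chaperones differed between media after air, and single genes did in lists that were not past the threshold by camera. Of these lists matrix and retinoid-responsive genes passed by fry with positive change (fry adjusted p = 0.00216 each). Stromal, immune and endothelial markers passed by fry with negative change (fry adjusted p = 0.0319). ER chaperones were higher in UNC for 8 of 13 and lower for 1 (camera adjusted p = 0.0199, adjusted p = 0.489 with an estimated correlation), with the secretory pathway transcription factor XBP1 at 0.94 ± 0.09 log2 units and the chaperone HSPA5 at 0.47 ± 0.06, both in 6 of 6 donors (edgeR adjusted p of 8.31e-05 and 2.96e-04). Matrix, protease and wound genes were higher for 6 of 18 and lower for 5 (6 adjusted over the list alone; camera adjusted p = 0.673, with a median of -0.13, a mean of -0.01 and a positive test direction). Within them the matrix glycoprotein TNC (1.94 ± 0.10, from 82.8 to 315 CPM), the integrin ITGA5 (1.27 ± 0.10) and TGFBI (0.85 ± 0.06) were higher, each in 6 of 6 donors. Cholesterol genes were higher for 6 of 21 and lower for 1 (camera adjusted p = 0.229), with the epoxidase SQLE at -0.89 ± 0.13. Of 10 retinoid-responsive genes 5 were higher and 2 lower (camera adjusted p = 0.22), with the binding protein CRABP2 at 1 ± 0.15 and the retinol transporter STRA6 at -1.24 ± 0.20.

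Heat shock genes went both ways between media, with 6 of 17 higher and 5 lower in UNC (6 lower adjusted over the list alone; camera adjusted p = 0.673, median -0.08, mean 0.01, negative test direction), and the chaperone HSP90AA1 fell by 0.64 log2 units. ATF4 targets were higher for 5 of 16 and lower for 3, and p53 targets higher for 4 of 12 and lower for 2 (camera adjusted p = 0.673 each), with the cytokine GDF15 at 1.89 ± 0.20 and PLK3 at -1.40 ± 0.06. The glucocorticoid list held GLUL, glutamine synthetase, at 1.43 ± 0.11 (1409 to 3754 CPM), and the interferon list RSAD2 at -1.15 ± 0.10. Stromal, immune and endothelial markers were higher for 2 of 9 and lower for 5 (camera adjusted p = 0.357), with the fibrillar collagen COL3A1 at 3.62 CPM in PneumaCult and 0.243 CPM in UNC (-4.20 ± 0.66). Mitochondrially encoded genes were higher for 6 of 13 (5 adjusted over the list alone; camera adjusted p = 0.110).

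After ozone in UNC cholesterol genes rose for 3 of 21 (camera adjusted p = 0.0465, adjusted p = 0.655 with an estimated correlation), with INSIG1 at 0.44 ± 0.08. Without the mixed pairs 1 of 21 rose (camera adjusted p = 0.0486, adjusted p = 0.685 with an estimated correlation). Among AHR targets TIPARP (0.30 ± 0.05) and CYP1B1 (0.90 ± 0.25, adjusted p = 0.0495) rose (2 of 7; camera adjusted p = 0.0846), and CYP1B1 was past the threshold without replicate 4 alone among the donors left out (up to 0.129 in the others). The EGFR feedback inhibitor ERRFI1 rose by 1.18 ± 0.20, the transcription factor ATF4 by 0.41 ± 0.07, and TP53INP1 and SCAI fell by 0.29 and 0.50 log2 units. Of 12 p53 targets 5 rose and 2 fell (camera adjusted p = 0.197). ER chaperones rose for 1 of 13 (median -0.03, mean 0.02, positive test direction), basal markers rose for 1 of 12 (median -0.07, mean 0.01, negative), and retinoid genes fell for 2 of 10 (median 0.04, mean -0.04, negative), with camera adjusted p from 0.589 to 0.629.

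Exchanging labels within donors gave 32 splits that part all 6 pairs, and for each comparison 1 of the 32, the real one, gave as many genes. This share is under 0.05 for each comparison taken alone. It is the smallest that 32 splits allow and was not adjusted over the comparisons. The real count and the highest of the other splits were 11158 and 0 between media after air, 35 and 0 for ozone in PneumaCult, 1958 and 1496 in UNC, 18 and 1 for the difference, and 11030 and 0 between media after ozone. Among 40 further splits that part fewer pairs the highest counts were 9060, 258, 946, 0 and 6179. Except for the difference, a pair that got the same label for both libraries no longer entered the contrast in these. Such a split tests the remaining pairs, with real or exchanged labels, and does not measure chance. In PneumaCult 1 of the 40, with 258 genes, exceeded the real 35. The source of that count was not tested, and the share of splits given for the 35 covers those that part all pairs only.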
